A study of Mus musculus with 6 samples.

How the data were processed

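Gene expression was measured in ovaries dissected from mouse embryos at embryonic day 15.5 (E15.5), with 3 arrays of a conditional knockout of Dmrt1 and 3 arrays of wild type. Per the labels' protocols, ovaries were collected into an RNA stabilising solution, total RNA was extracted with a column kit, and biotin-labelled RNA was hybridised to Affymetrix arrays. The labels number the samples of each group as replicates 1 to 3 and say nothing about separate animals or litters, the strain, or the Cre line behind the conditional removal.

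The deposited values are intensities per probe set on a linear scale, never negative, with array medians between 13.2 and 14.7. The authors made them with GCRMA, a background adjustment, normalization and summary of probes by their base composition, per the submitters' processing notes, which give no version or settings. Such values carry no detection calls and no spot counts, so the number of arrays limits the precision. GCRMA presses dim probe sets towards a floor, which widens fold changes near it and gives little meaning to differences between dim values.

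The deposited intensities were taken to log2. Of 45101 probe sets, 64 control probe sets were left out. A probe set was tested when its log2 value was at least 4 (an intensity of 16) on at least 3 of the 6 arrays, whichever their group, which left 22040. Gene symbols came from the platform annotation, brought up to date by gene identifier through a RefSeq gene table of assembly GRCm38.p6. That table held 34741 of the 34945 probe sets with a single gene, and 0 symbols changed. A further 932 probe sets named several genes and 9160 were unnamed, and neither kind was used to name a gene. Among tested probe sets, 19541 named 1 gene, 564 several and 1935 none. No reference sequence was used here.

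Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, genotype as the only term, 2-sided). P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. A gene was counted once, through the probe set with the highest mean over all 6 arrays, which gave 11897 genes. Where all 3 arrays of a group lay under the filter level of log2 4, the fold is given as at least the ratio of the brighter group's mean to that level. Where some of them did, the number is given, and those arrays were set at the level for the fold. Errors of differences are limma's moderated standard errors.

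There were 20 gene lists, holding 372 genes, of which 336 were on the array and 272 were tested, 2 of them matched through a synonym. The 19 lists other than the sex chromosome check were tested with camera at its preset correlation of 0.01, one probe set per gene, adjusted over the lists. Each list was also tested with an estimated correlation and with fry. The genes named are 11 chosen for the question, the 10 with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, and up to 3 members of each list with the smallest p. This made 81 genes, and names outside that rule are marked as chosen after their values were seen. The samples, the lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined.

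The steps were tested on simulated arrays with the spread of the real ones, 22040 probe sets and 200 changed genes. The fit recovered 4 of 50 genes changed by 0.5 log2 units, 26 of 50 changed by 1, 47 of 50 changed by 2 and 50 of 50 changed by 3, with 0 of the wrong sign and 3 unchanged probe sets called. Of simulated lists without a shift, 3.5% had an unadjusted p under 0.05. Simulated probe sets varied independently of each other, while the real lists had estimated correlations of -0.108 to 0.701. That share therefore does not check the preset correlation on correlated genes.

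Alternatives covered no filter and a stricter filter, eBayes without the trend and in its robust form, array weights, the replicate number as a block, quantile normalization, median centring, leaving out probe sets that can match several transcripts, the mean of a gene's probe sets, other thresholds, other list tests, and leaving out each array in turn. Added after seeing the data were a fit without the knockout array that lacked Xist signal, a fit on probe sets with 1 gene, and a fit on autosomal genes. The fit was repeated for all 10 splits of the 6 arrays into 3 and 3. Replicates of a group were compared before averaging, and 0 pairs of arrays held identical values.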

Results

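Ovaries of E15.5 mouse embryos were profiled on 6 arrays, 3 from a conditional knockout of Dmrt1, a transcription factor of the DM domain family that acts in germ cells and testis, and 3 from wild type. The comparison asked which transcripts differ when Dmrt1 is removed from the fetal ovary at an age when its germ cells are in meiotic prophase. Log2 values correlated at 0.986 to 0.993 within groups and at 0.973 to 0.980 between groups, and the leading principal component, with 55.9% of the variance, separated the groups. Array medians were 13.2 to 13.4 intensity units in knockout and 14.4 to 14.7 in wild type. The labels do not say that replicates came from separate animals, so all p-values measure the spread between these samples, which may be technical.

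Dmrt1 itself was close to the floor on every array. Its probe set read 8.55, 5.97 and 7.46 intensity units on knockout replicates 1, 2 and 3 and 8.47, 8.51 and 13.0 on wild-type replicates 1, 2 and 3. The mean log2 difference of -0.43 lay between groups that overlapped (log2 2.86 ± 0.26 against 3.29 ± 0.36, SD, n = 3 each), below the level at which probe sets were tested. The position of this probe set relative to the deleted part is not known here, so Dmrt1 neither checks nor contradicts the genotype labels.

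Xist, the RNA that silences 1 X chromosome in female cells, was near the floor on knockout replicate 1 alone. Its 3 probe sets averaged log2 1.81 on that array, against 9.85 and 9.75 on knockout replicates 2 and 3 and 10.7 to 10.9 on the wild-type arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty were at the floor on all 6 arrays, with array medians of log2 1.29 to 1.49 over 9 probe sets. Counts are therefore also given without knockout replicate 1.

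**Figure D1:**
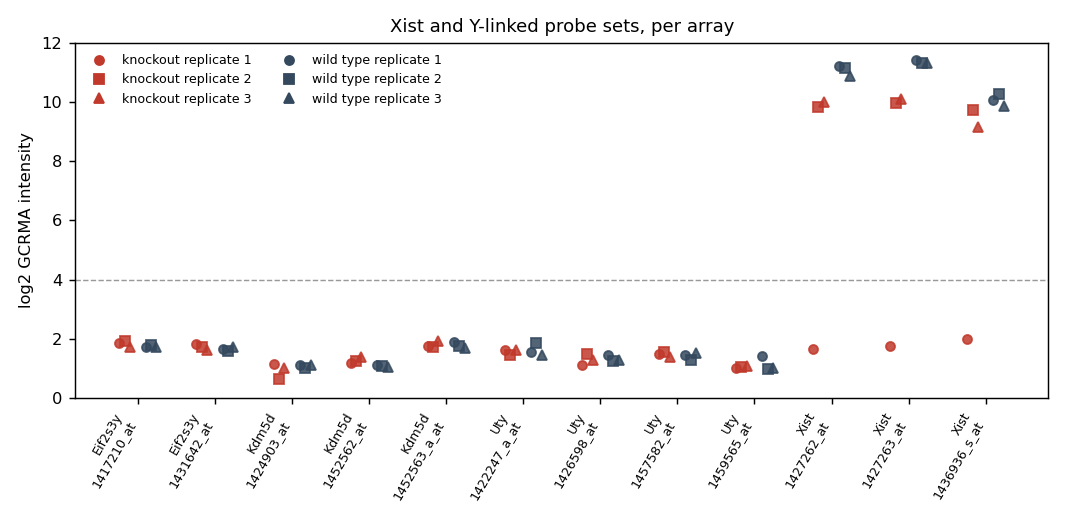
Log2 GCRMA intensity (vertical axis) of each Xist and Y-linked probe set (horizontal axis), with 1 point per array, red for knockout and dark blue for wild type, and the filter level of log2 4 as a dashed line. Xist averaged log2 1.81 on knockout replicate 1 and 9.75 to 10.9 on the other 5 arrays, while Y-linked probe sets lay at the floor on all 6.

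In the list of pluripotency and early germ cell genes, 6 of 15 tested members rose in the knockout ovaries, Sox2, Dppa2, Dppa4, Dppa5a, Lin28a and Sall4. Dppa4 and Dppa5a lay outside the rule for named genes. Sox2, a pluripotency transcription factor, rose at least 5.28-fold (log2 difference 3.75 ± 0.69, SE, n = 3 per group), and Dppa2, a chromatin protein of pluripotent cells, rose at least 9.46-fold (4.05 ± 0.65). Lin28a, an RNA-binding protein that blocks let-7 processing, rose 9.48-fold (3.24 ± 0.63), and Sall4, a zinc finger factor of early germ cells, rose 7.68-fold (2.94 ± 0.52). Outside that list, Dppa3, also known as Stella and counted with the oocyte genes, rose 15.49-fold with the 2 of its 3 wild-type arrays that lay under the filter level set at it (fitted difference 4.22 ± 0.76). Cdx2, a factor best known from trophectoderm and gut and a member of 0 lists, rose 12.49-fold (3.64 ± 0.72). The limma adjusted p for Sox2, Dppa2, Lin28a, Sall4, Dppa3 and Cdx2 ran from 0.00435 to 0.0139. These 6 were most abundant on knockout replicate 1 and least abundant on knockout replicate 3, with SDs of 1.2 to 2.0 log2 units among the knockout arrays.

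In that list 0 genes fell and 9 did not pass the test. Both tested probe sets of Lin28a rose. Adjusted over the list alone, 9 rose. Pou5f1 (log2 difference 1.53 ± 0.52, limma adjusted p = 0.122) and Nanog (1.47 ± 0.52, limma adjusted p = 0.139) did not pass, except with array weights (0.042 and 0.0378) and without knockout replicate 3 (0.0272 and 0.0151). Without knockout replicate 1 their differences were 0.83 and 0.75 (limma adjusted p = 0.201 and 0.231). The list's median difference was 1.47 (camera adjusted p = 5.02e-07), and the list did not pass with an estimated correlation (0.414) or with fry (0.202). Without knockout replicate 1 the median was 0.75, 6 genes rose, and the camera adjusted p was 3.99e-07, or 0.561 with an estimated correlation. Without wild-type replicate 1, Sox2, Cdx2 and Lin28a were no longer past the threshold (limma adjusted p = 0.0523, 0.0713 and 0.0581), and with robust eBayes the same held for Dppa3 and Cdx2 (0.0625 and 0.0832).

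**Figure D2:**
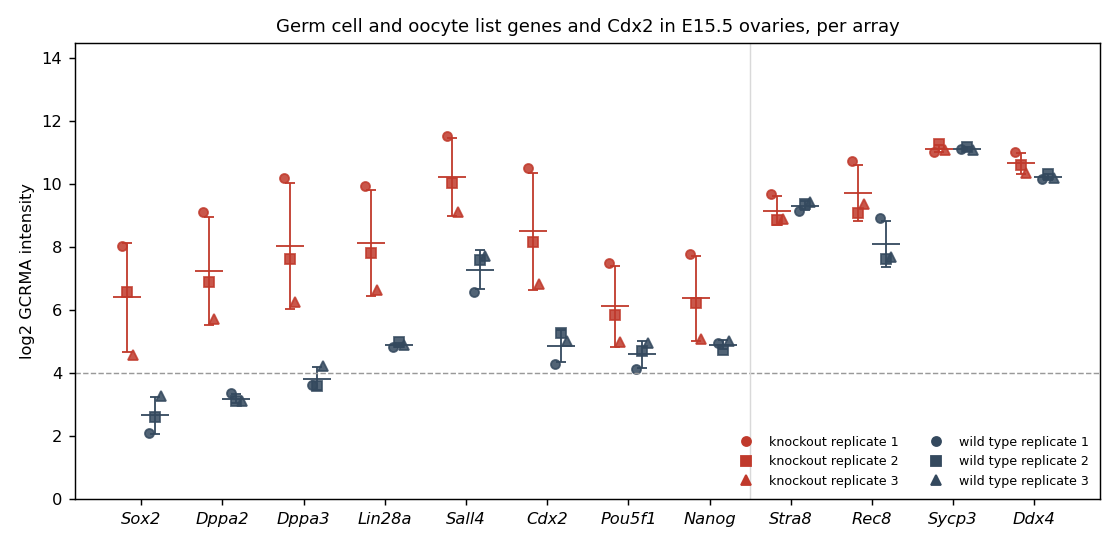
Log2 GCRMA intensity (vertical axis) of Cdx2 and 11 genes of the germ cell and oocyte lists (horizontal axis) on each array, knockout in red and wild type in dark blue, with horizontal bars for means, error bars for the SD of 3 arrays and a dashed line at the filter level of log2 4. Sox2, Dppa2, Dppa3, Lin28a, Sall4 and Cdx2 lie higher on all 3 knockout arrays and spread widely among them, while Stra8 and Sycp3 overlap between groups.

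Of 21 tested genes that act in germ cells and in the piRNA pathway, which silences transposons, 4 rose and 17 did not pass. Piwil4, a PIWI protein of fetal germ cells, rose 6.58-fold (log2 difference 2.72 ± 0.37, SE, n = 3 per group, limma adjusted p = 0.00174). Its tested probe set is of the kind that can match several transcripts. The other Piwil4 probe set lay under the filter level, at log2 1.82 in knockout and 1.63 in wild type. Tex19.1 rose 3.29-fold (1.72 ± 0.37, 0.0216) and Pld6, a mitochondrial enzyme of piRNA production, rose 1.90-fold (0.93 ± 0.20, 0.0194). Tdrd12 (0.83 ± 0.21, 0.0404), which lay outside the rule for named genes, completed the 4. In this list 0 fell and 6 rose adjusted over the list alone. Ddx4, the germ cell helicase also called Vasa, differed by 0.43 ± 0.16 (limma adjusted p = 0.161, and 0.046 without knockout replicate 3). Without knockout replicate 1 its difference was 0.25 (limma adjusted p = 0.374). The median was 0.43 (camera adjusted p = 8.25e-05), and the list did not pass with an estimated correlation (0.414) or with fry (0.21). Without knockout replicate 1 the median was 0.17 and 2 genes rose. Piwil4 kept its call without any single array, while that of Pld6 ended without knockout replicate 1 or wild-type replicate 1 or 2, and that of Tex19.1 without wild-type replicate 1 or 3.

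The macrophage, endothelium and stroma lists, described further on, had median differences of -0.33, -0.22 and -0.22, with 2 of 13, 2 of 11 and 0 of 17 genes past the threshold. None of the 3 lists passed with an estimated correlation, and the macrophage median was -0.09 without knockout replicate 1. The 3' minus 5' log2 difference of the Gapdh control probe sets, a sign of RNA integrity, was 1.13 to 1.52 in knockout and 0.99 to 1.30 in wild type. For beta-actin it was 2.45 to 2.75 in knockout and 2.28 to 2.74 in wild type, so both ranges overlapped.

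Genes of meiotic prophase showed no call through their brightest probe sets. Stra8, which germ cells need to enter meiosis, differed by -0.17 ± 0.21 log2 units (SE, n = 3 per group, limma adjusted p = 0.705) at a mean log2 of 9.16 ± 0.46 (SD) in knockout and 9.33 ± 0.14 in wild type. Knockout replicate 1 read log2 9.69, above the wild-type arrays (9.17 to 9.43), and knockout replicates 2 and 3 read 8.87 and 8.90, below them. Without knockout replicate 1 Stra8 differed by -0.44 and did not pass (limma adjusted p = 0.158). Sycp3, a component of the synaptonemal complex, differed by 0.00 ± 0.10 (0.987). Rec8, the meiotic cohesin, was higher on all 3 knockout arrays than on any wild-type array, by 1.64 ± 0.44, and did not pass (0.0538). It passed with no filter (0.0449), with array weights (0.0179), without probe sets that can match several transcripts (0.0442), and without knockout replicate 2 (0.0358) or wild-type replicate 1 (0.0311). Rec114, a partner of the meiotic break machinery, did not pass through its brightest probe set (0.37 ± 0.10, 0.0508), while its other tested probe set rose by 0.88 ± 0.21 (0.0356). 4930432K21Rik (0.83 ± 0.22, 0.0525), the current name here of Brme1, did not pass. Both genes passed with no filter (0.0485 and 0.0465), array weights (0.0398 and 0.0392) or median centring (0.0484 and 0.0498), and without probe sets that can match several transcripts (0.0294 and 0.0442). Rec114 also passed with quantile normalization (0.0443) and with averaged probe sets (0.0444), and 4930432K21Rik without knockout replicate 2 (0.0331). Of 37 tested genes, 0 rose and 0 fell, against 5 that rose and 1 that fell adjusted over the list alone and 11 with an unadjusted p under 0.05. The median was 0.06 (camera adjusted p = 0.284). The list passed without knockout replicate 2 (0.0489) and without wild-type replicate 2 (0.0047). Without knockout replicate 1 its median was -0.003 (camera adjusted p = 0.855), and with an estimated correlation on all arrays the adjusted p was 0.79.

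Among genes of oocyte differentiation, Dppa3 and Ooep rose and Jag1 fell. Ooep, a component of the maternal cytoplasmic complex of the egg, rose 2.50-fold (log2 difference 1.32 ± 0.28, SE, n = 3 per group, limma adjusted p = 0.0189), and Jag1, a Notch ligand of oocytes, fell by 0.50 ± 0.10 (0.0175). The other 7 of 10 tested genes did not pass. Adjusted over the list alone, 4 rose and 1 fell, and the list did not pass (median 0.35, camera adjusted p = 0.119). It passed with no filter (0.0131) and without wild-type replicate 2 (0.0278). The Jag1 call ended with eBayes without the trend (limma adjusted p = 0.0513) and without any one of knockout replicate 1 or the 3 wild-type replicates, and that of Ooep without wild-type replicate 2 or 3.

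Somatic ovary genes showed few calls. Foxl2, the factor that keeps granulosa cell identity, differed by -0.26 ± 0.27 (SE, n = 3 per group, limma adjusted p = 0.637), and Fst, encoding follistatin, by 0.24 ± 0.14 (0.376). Without knockout replicate 1 they differed by -0.55 (limma adjusted p = 0.241) and 0.12 (0.697). Of 16 tested pregranulosa genes 0 passed, also adjusted over the list alone, and 4 had an unadjusted p under 0.05. The lowest p in that list belonged to Irx5 (0.72 ± 0.20, 0.0601, and under 0.05 in 4 of the other fits), Nr0b1 (0.58 ± 0.22, 0.162) and Amhr2 (0.25 ± 0.10, 0.172), and its median was 0.16 (camera adjusted p = 0.0816).

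In the Sertoli and testis list, Tesc, which encodes the calcium-binding protein tescalcin, rose at least 3.0-fold (1.88 ± 0.27, SE, n = 3 per group, limma adjusted p = 0.00243). The other 14 of 15 tested genes did not pass, and 1 rose adjusted over the list alone (median 0.05, camera adjusted p = 0.568). Sox9, the factor that directs Sertoli cell fate, differed by -0.43 ± 0.18 (0.217) at low levels in both groups. Of 8 steroidogenic genes 0 passed, 1 rose adjusted over the list alone and 4 had an unadjusted p under 0.05, with Nr5a1, a regulator of steroid synthesis, at 0.50 ± 0.14 (0.0694). The median of that list was 0.29 (camera adjusted p = 0.119).

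Lists of stroma, blood vessel and immune markers had negative medians in knockout. Of 17 stroma and mesenchyme genes 14 had a negative difference, and 0 passed through the brightest probe set, also adjusted over the list alone, while 6 had an unadjusted p under 0.05. For 5 of the 17 another probe set fell. Dcn differed by -0.35 ± 0.10 (SE, n = 3 per group, limma adjusted p = 0.0716) and its other probe set fell by 1.76 ± 0.26 (0.00282), while Col1a1 differed by -0.25 ± 0.07 (0.0806) and its other probe set fell by 0.54 ± 0.14 (0.0446). Dcn passed with averaged probe sets (fell by 1.06, 0.0161), with array weights (0.0266) and without knockout replicate 3 (0.017). That list's median was -0.22 (camera adjusted p = 0.000865), with adjusted p = 0.414 with an estimated correlation. In endothelium, the receptors Flt1 (fell by 0.88 ± 0.19, limma adjusted p = 0.0184) and Tek (fell by 0.51 ± 0.13, 0.0452) passed and the other 9 of 11 did not, with 3 falling adjusted over the list alone. Its median was -0.22 (camera adjusted p = 0.0169), with adjusted p = 0.414 with an estimated correlation. The list did not pass without knockout replicate 2 (0.16) or wild-type replicate 3 (0.0576), and the Flt1 call ended without wild-type replicate 3 (limma adjusted p = 0.0911). That of Tek ended under the stricter filter (0.0609), eBayes without the trend (0.0616), quantile normalization (0.0537), median centring (0.0507) and averaged probe sets (0.0525).

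All 13 macrophage and immune genes had a negative difference. Ptprc, the leukocyte marker CD45, fell by 1.06 ± 0.25 (SE, n = 3 per group, limma adjusted p = 0.0357), with 1 knockout array under the filter level, and Mrc1, a mannose receptor, fell by 0.72 ± 0.17 (0.0358), while 11 did not pass and 3 fell adjusted over the list alone. The median was -0.33 (camera adjusted p = 0.000358), with adjusted p = 0.414 with an estimated correlation. Without knockout replicate 1 the median was -0.09, 0 genes fell, and the list no longer passed (camera adjusted p = 0.0541). The calls of Tek, Ptprc and Mrc1 each ended on leaving out any of 5 of the 6 arrays. In the erythroid list Slc4a1, the red cell anion exchanger, fell by 1.44 ± 0.33 (limma adjusted p = 0.0275, and over 0.05 without knockout replicate 1 or 2 or wild-type replicate 1 or 3), and the other 5 of 6 did not pass, with 1 falling adjusted over the list alone (median -0.63, camera adjusted p = 0.0733). That list passed with the stricter filter (0.0321), without probe sets that can match several transcripts (0.0106), with averaged probe sets (0.041) and without wild-type replicate 2 (0.00616). The Slc4a1 and Mrc1 calls ended with eBayes without the trend (limma adjusted p = 0.0564 and 0.0678), that of Ptprc with quantile normalization (0.0629), and those of Ptprc and Mrc1 with averaged probe sets (0.06 and 0.0581).

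Lists of neighbouring tissues did not pass. Of 9 genes of the mesonephros and ducts 0 passed (median 0.08, camera adjusted p = 0.392), with Lhx1, a factor of the nephric duct, at 0.41 ± 0.19 (SE, n = 3 per group, limma adjusted p = 0.255). Of 10 genes of the ovarian surface epithelium 0 passed (median 0.14, camera adjusted p = 0.138), with Lrrn4 at 0.46 ± 0.15 (limma adjusted p = 0.109). In both lists 0 genes passed adjusted over the list alone, and 0 and 3 had an unadjusted p under 0.05.

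Of 18 WNT and BMP target genes, Msx1, a homeobox gene induced by BMP, rose 1.74-fold (0.80 ± 0.18, SE, n = 3 per group, limma adjusted p = 0.0247), and 17 did not pass, with 1 rising adjusted over the list alone. The median was 0.21 (camera adjusted p = 0.0213), with adjusted p = 0.414 with an estimated correlation, and the list did not pass with the stricter filter (0.0719), without probe sets that can match several transcripts (0.0556), or without knockout replicate 1 (0.138) or 2 (0.0703) or wild-type replicate 1 (0.0692). In the DMRT family Dmrta1 rose 1.60-fold (0.68 ± 0.17, limma adjusted p = 0.0452), the other 3 of 4 did not pass, and 2 rose adjusted over the list alone. The median was 0.46, or 0.39 with Dmrta2, under the filter level in wild type, at its bound (camera adjusted p = 0.0148), and the list did not pass with no filter (0.189) or with an estimated correlation (0.414). The Msx1 and Dmrta1 calls both ended without knockout replicate 1 and without each of the wild-type replicates in turn, and that of Dmrta1 also without knockout replicate 3, under the stricter filter (limma adjusted p = 0.056) and with averaged probe sets (0.0542).

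In the mitotic cell cycle list Mcm3, a subunit of the replicative helicase, rose 1.48-fold (0.56 ± 0.11, SE, n = 3 per group, limma adjusted p = 0.0151), and 24 of 25 did not pass. Adjusted over the list alone, 4 rose and 1 fell (median 0.12, camera adjusted p = 0.0812), and the list passed with array weights (0.0322), with averaged probe sets (0.0113), and without knockout replicate 3 (0.0115) or wild-type replicate 2 (0.0459). Among 14 genes of the p53 response Bcl2l11, the pro-apoptotic protein BIM, fell by 0.60 ± 0.13 (limma adjusted p = 0.0216) and 13 did not pass, with 1 falling adjusted over the list alone. Both calls ended without knockout replicate 1 (limma adjusted p = 0.0534 and 0.0572) and without wild-type replicate 1 or 2, and that of Bcl2l11 also without wild-type replicate 3. With averaged probe sets both ended too (0.105 and 0.0967). The p53 list did not pass (camera adjusted p = 0.498), and its median of 0.01 and mean of -0.05 differed in sign.

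Of 13 genes of retinoic acid metabolism and response, the pathway that induces Stra8, 0 passed, also adjusted over the list alone and at an unadjusted p under 0.05 (median -0.02, mean -0.01, camera adjusted p = 0.95 with the test's direction upward). Of 10 immediate early and stress genes 0 passed, 1 fell adjusted over the list alone and 3 had an unadjusted p under 0.05 (median 0.02, mean -0.03, camera adjusted p = 0.932 with the test's direction downward). Egr1, an immediate early factor, differed by -0.52 ± 0.14 (SE, n = 3 per group, limma adjusted p = 0.0552, and 0.0476 without probe sets that can match several transcripts).

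**Figure D3:**
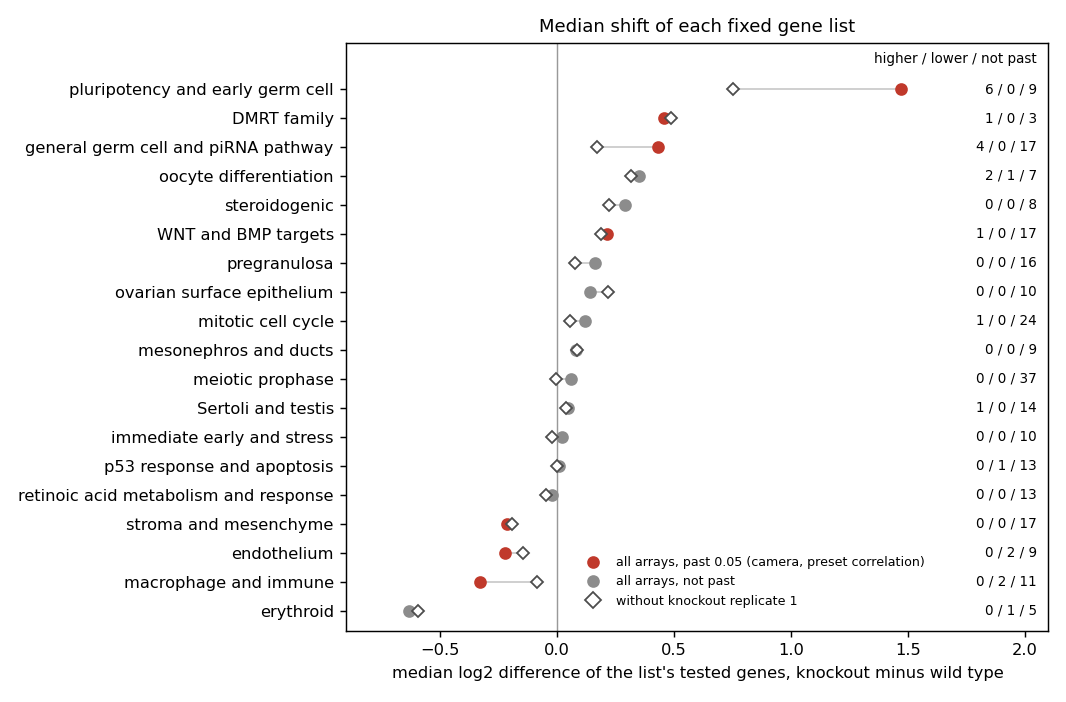
Median log2 difference of the tested genes of each list, knockout minus wild type (horizontal axis), for 19 lists (vertical axis). Circles use all arrays, red where camera passed 0.05 with the preset correlation, open diamonds leave out knockout replicate 1, and the numbers at the right count members that were higher, lower or not past the threshold. The pluripotency and early germ cell list had the highest median, 1.47, or 0.75 without that array.

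Among list genes not called through the brightest probe set, another tested probe set was higher for 4 and lower for 7 (limma). In all, 7 of the 19 lists passed with the preset correlation, 0 with an estimated correlation (0 also unadjusted) and 0 with fry in a single direction (4 unadjusted), while fry for change in either direction passed 13. Without knockout replicate 1, 5 passed with the preset correlation and 0 with an estimated correlation.

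Across all genes, 152 rose and 270 fell in the knockout, 422 of 11897 tested (limma, adjusted p under 0.05). In a fit on probe sets with 1 gene alone, 284 of the 422 were called. Counted over all tested probe sets the excess of falls was larger, with 321 higher and 1134 lower. Of these, 228 and 655 named 1 gene. The excess of falls among genes depended on the filter, since with no filter 380 rose and 347 fell. It also lay mostly among long genes: in the longest of 5 equal groups by length, 22 rose and 142 fell. From short to long, the other groups had 55 rises and 30 falls, 26 and 24, 24 and 32, and 23 and 40. At least 2-fold, 59 rose and 70 fell. Without knockout replicate 1 the count was 253, with 86 higher and 167 lower, and 215 genes were called in both. Groups did not overlap for 2819 genes (23.7%, where chance gives 10%). Leaving out wild-type replicate 1, 2 or 3 gave 162, 158 and 174 genes. Of the called genes, 165 had another tested probe set, and for 133 of these every other probe set differed in the same direction.

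The largest fitted rises belonged to 2 genes that were uniform among knockout arrays. Gm3715, a predicted gene, rose at least 33.6-fold (log2 difference 7.10 ± 0.16, SE, n = 3 per group, limma adjusted p = 1.21e-08), and the transcript 4933438K21Rik rose at least 33.2-fold (6.57 ± 0.17, 1.56e-08). Mup10, of the major urinary protein cluster, rose 10.2-fold with its 1 wild-type array under the filter level set at it (fitted difference 3.62 ± 0.29, 0.000108), and Ptprj, a receptor tyrosine phosphatase, rose at least 4.17-fold (3.21 ± 0.29, 0.000196). These 4 genes were each read by 1 tested probe set and kept their calls without any single array. Further Ptprj probe sets, under the filter level on all arrays, differed by -0.01 to 0.31. Mup10, like Amy1 among the falls, belongs to a family of near-identical copies, so its signal may include other members.

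The 10 genes with the largest fitted falls included 5 with knockout arrays under the filter level, so their order is no ranking. The transcript 4930563E18Rik, under that level on all 3 knockout arrays, was at least 2.38-fold lower (fitted difference -3.30 ± 0.31, SE, n = 3 per group, limma adjusted p = 0.000226). Gm13306 was at least 2.84-fold lower and Tshb, the beta subunit of thyrotropin, at least 2.31-fold. With 2 knockout arrays each under that level and set at it, 2310067E19Rik was 6.41-fold lower (fitted difference -2.74 ± 0.32, 0.000813) and Camk4, a calcium and calmodulin-dependent kinase, 4.09-fold (-2.18 ± 0.24, 0.000639). Insyn2a, an inhibitory synapse protein, fell by 2.50 ± 0.19 (limma adjusted p = 6.60e-05). These falls of Camk4 and Insyn2a were each read by 1 tested probe set. Their other probe sets, under the filter level on all arrays, differed by -0.12 to 0.37 for Camk4 and by 0.18 and 0.07 for Insyn2a. Atp2b4, a plasma membrane calcium pump, fell by 1.80 ± 0.23 (0.00131), and Zfp950 fell by 1.64 ± 0.21 (0.00141). The other 2, 5031426D15Rik and Amy1, fell by 1.97 and 1.66. All 10 kept their calls without any single array, and Zfp950 lost its own when the probe sets of each gene were averaged (limma adjusted p = 0.0536).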

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

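The tests of Y-linked signal, of long genes and of sequence differences at the probes were chosen after the results they bear on had been seen; the others in this part were chosen before.

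Among tested probe sets that name no single gene, 93 rose in the knockout, a signal in data outside the comparison of genes. Among unnamed probe sets the larger part ran the other way: of 1935, 470 fell and 76 rose. Their median difference was -0.21, against 0.01 for probe sets with 1 gene. Of 564 probe sets naming several genes, 17 rose and 9 fell. Rises made up 3.93% of unnamed probe sets and 3.01% of those naming several genes, against 1.17% of those with 1 gene. The cause of these rises was not tested. Quantile normalization left unnamed minus named at -0.193, against -0.221 before, and probe sets of the same brightness gave -0.214. These values argue against an intensity-dependent shift left by the authors' normalization and against low brightness. Other effects of the processing on unnamed probe sets were not tested. Genomic DNA or unspliced RNA in the wild-type samples would raise the B1 and B2 repeat controls there, and none of these 3 probe sets was lower in knockout on average. They differed by 0.313, 0.347 and 0.0575 log2 units, a mean of 0.239, and the last overlapped between groups. Control probe sets for the non-mouse sequences BioB, BioC and BioD were higher in knockout as well, by 0.101 to 0.248. Those for cre differed by -0.0309 to 0.0906. With differences of that size in controls that read no mouse RNA, the repeat controls cannot decide. More unspliced RNA read across long genes cannot be told apart from a genotype effect, since the median difference of the 2372 longest genes minus that of the 2372 shortest was -0.165, between the bounds set for either reading.

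Xist was at the floor on knockout replicate 1, as measured by all 3 of its probe sets. A male embryo is argued against, because the Y-linked median of that array was -0.0155 log2 units from the highest other array. A general failure is argued against too, since only 3 probe sets, all of Xist, read over 4 log2 units below every other array. The 8 tested genes that escape X inactivation were lower there by a median of -0.344, relative to autosomal genes and the other knockout arrays. Against the other knockout arrays the 8 ranged from -0.0183 to -1.01 log2 units. The same median on the other 5 arrays was -0.07 to 0.32, so an embryo with a single X chromosome is a candidate explanation. A lesion of the Xist locus itself was not tested and stays open, and the value of 0.32, of knockout replicate 2, is itself raised by its comparison with replicate 1.

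Some very large changes sat on single probe sets. Of 39 probe sets called and changed over 8-fold, 14 named 1 gene, and 4 of the genes so named had another tested probe set. Kif5b, Minar2 and Lman1, outside the rule for named genes, fell by 5.27, 5.38 and 4.29 log2 units on 1 probe set each. Of their 9 other tested probe sets, 0 changed over 2-fold the same way (0%). The Minar2 probe set that fell is of the kind that can match several transcripts. SDs of the 3 falls were 0.155 to 0.731 log2 units among knockout arrays and 0.597 to 0.69 among wild-type arrays. A sequence difference between the groups at these probes is a candidate, but the labels give no strain. Other causes limited to 1 probe set were not tested. For Lin28a both probe sets rose together (100%), which argues against it there, while the other 8 rises with 1 gene had no further tested probe set. Of these, Sox2, Dppa2, Dppa3 and Cdx2 varied among the knockout arrays in the same order as Lin28a, with SDs of 1.7 to 2.0 log2 units, where a fixed sequence difference alone would give an even offset. Gm3715, 4933438K21Rik, Mup10 and Ptprj, with SDs of 0.0304, 0.109, 0.205 and 0.601, stay open. A segment around Dmrt1 carried along with the deleted allele was looked for among the 100 nearest tested genes. Of these, 3 were called, 0.845 times the share of all other genes (3.55%). The called genes were Pgm5, Fam122a and Ptar1, outside the rule for named genes, with log2 differences of -1.11, 1.38 and -0.83. So few calls in so wide a window show no excess across it and cannot decide on a shorter segment.

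The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 422 genes with limma and the highest other split 0 (at an unadjusted p under 0.05, 2076 and at most 895), so that 1 of the splits, the real one, reached that count. For gene lists the real split gave 7 and the highest other 8, and 3 of the splits, the real one included, reached that count.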

How the results depend on the processing

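The fits on autosomal genes, on probe sets with 1 gene and without the array lacking Xist signal were chosen after the data were seen. Across all settings, 0 results of named genes or lists turned their sign past the threshold. Of 35 named genes called, 24 kept the call at an adjusted p under 0.05 under every fit tried in which they were tested, left-out arrays and the 2-fold thresholds aside, and 19 kept it without any single array. The fit without probe sets that can match several transcripts tested 31 of the 35. Named genes include the largest changes by rule, so their share does not stand for all calls. Of all 422 called genes, 144 to 166 stayed called without 1 wild-type array and 215 to 320 without 1 knockout array. With an array left out, 158 to 555 genes were called, with 58 to 227 higher and 100 to 328 lower, and 5 to 11 lists passed. The highest count, 555, came without knockout replicate 2, for which the cause was not tested; the fits without an array have fewer samples. Without the array lacking Xist signal 253 were called, 86 higher and 167 lower. No filter gave 727 genes, 380 of them higher (52.3%, against 36.0%), with 18193 genes tested, and the stricter filter gave 248 (79 higher, 169 lower), with 9748 genes tested. Quantile normalization gave 44.8% higher. Array weights gave 235 higher; the cause was not tested. Probe sets with 1 gene gave 284 called, 100 higher, all 284 among the 422, and autosomal genes gave 276 called, 96 higher. Both fits left out the unnamed probe sets, of which 24.3% fell in the main fit, against 3.35% of those with 1 gene. The adjustment thus ran over a set with a smaller share of calls. In both fits the calls of Tek, Ptprc, Mrc1 and Dmrta1 ended. Thresholds of adjusted p and at least 2-fold gave 129 (59 higher, 70 lower), unadjusted p and 2-fold 168 (72 and 96), and an adjusted p under 0.1 gave 838 (331 higher, 507 lower). With an estimated correlation 0 lists passed (0 unadjusted), and with fry 0 (4 unadjusted). Replicate numbers do not pair the samples, with correlations of deviations of -0.165, -0.247 and -0.168 for equal numbers. Unequal numbers gave -0.148 to 0.336. The positive values were 0.328 (knockout replicate 1 with wild-type 2), 0.336 (2 with 3) and 0.238 (3 with 1). A factor shared across groups in that order was not tested. The replicate block gave 220 genes (83 higher, 137 lower) and 9 lists, with oocyte differentiation (camera adjusted p = 0.0398), the erythroid list (0.0234) and Rec8 (limma adjusted p = 0.000631) past it and the calls of Jag1, Tek, Ptprc, Mrc1, Mcm3, Bcl2l11 and Dmrta1 ended; it leaves fewer degrees of freedom. Signal over background limits dim genes: Dmrt1, under the filter level on all arrays, differed by -0.23 to -0.55 with an array left out.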

Other observations

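The genes of the next 2 paragraphs and the test of knockout replicate 1 were chosen after their values had been seen.

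Of 4 tested genes of the X-linked Rhox cluster, a group of homeobox genes active in germ cells and placenta, 3 rose in the knockout, and the cluster was not tested as a list. Rhox5 was higher by 2.34 ± 0.41 log2 units (SE, n = 3 per group, limma adjusted p = 0.00753), Rhox9 by 2.25 ± 0.27 (0.000884) and Rhox6 by 2.06 ± 0.25 (0.000887), on all 3 knockout arrays against all 3 wild-type arrays. Rhox13, the other tested member, differed by 0.11 ± 0.11 (0.635). Quantile normalization and median centring left all 4 differences positive, and without knockout replicate 1 they were 1.72, 1.87, 1.78 and 0.09. Of 416 tested X-linked genes, 7 rose and 13 fell, 4.81% in all.

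Some probe sets of long non-coding RNAs kept in the nucleus were lower, a group picked after its values were seen and not tested as a list. Counted through the brightest probe set, 2 of 10 such RNAs fell. Of 30 tested probe sets of these RNAs, 10 fell, 0 rose and 27 had a negative difference, with a median of -0.46 (limma). After quantile normalization and after median centring, 27 stayed negative. Airn, an antisense RNA of an imprinted cluster, fell by 1.24 (adjusted p = 0.0014) and Neat1, the scaffold of paraspeckles, fell by 0.84 (0.0286), while Malat1 differed by 0.02 (0.949) on its brightest probe set. Several of the falls, such as that of Kcnq1ot1 by 2.41 on 1 probe set, were not shared by the brightest probe set of the same RNA, which differed by 0.06. Gene length went with direction as well: among the 2372 longest genes 142 fell and 22 rose, and among the 2372 shortest 30 fell and 55 rose.

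The rise of 6 pluripotency genes could come from knockout replicate 1 alone, the array without Xist signal, on which these genes were most abundant. Without that array the median difference of the list was 0.754, 51.3% of its value of 1.47 with all arrays, and the 6 genes still rose. Among them Dppa2, Lin28a, Sall4 and Sox2 rose by 3.12, 2.34, 2.28 and 2.93 log2 units (limma adjusted p = 0.0011 to 0.0133). The array thus adds to the size of the shift, and these values argue against it as the only source of the rise of the 6 genes. Why the knockout arrays differ among themselves was not tested.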
